A study of Homo sapiens with 3 samples.

How the data were processed

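Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map heat shock factor 1 (HSF1), the transcription factor that drives the heat shock response, in NK-92 MI cells, an interleukin-2 independent derivative of the human natural killer (NK) lymphoma line NK-92. The series lists 3 samples, which were grouped by their titles: 1 HSF1 immunoprecipitation with no treatment given, 1 input, and 1 HSF1 immunoprecipitation from cells held at 42 °C for 1 h before use. Peak files of the heat-shocked library were analysed; the other immunoprecipitation and the input were not analysed here. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sheared by Covaris sonication, and low-input DNA libraries were made from the HSF1 precipitate. Per the submitters' processing notes, Bowtie2 2.3.4.1 and ChIPseeker were used and the genome build was hg38. The peak caller, its threshold and whether the input served as its control are not given in the sources used here.

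The authors deposited 2 peak lists for this library, and each peak carries a score of its own whose definition is not given in the file headers or labels. The first list has no header; its positions and its contig names are those of hg38. The second is, per the file headers, a ChIPseeker annotation table that adds 1 nearest gene, the signed distance to its transcription start site (TSS) and a genomic feature to each peak. The positions in this table are not on hg38: of 2516 genes compared with the RefSeq table of GRCh38.p14, 96 (3.82%) began within 1000 bp of the RefSeq position. Its gene positions and UCSC transcript names were read here as those of the older build hg19 (GRCh37), which no label names. Coordinates below carry the build of the list they come from, and none was converted. The lists hold peaks of 1 library and were not pooled by the labels. The running peak numbers reach 3455 in the hg38 list and 3446 in the annotated table, and skip 17 and 50 values; peaks with those numbers were not analysed here, so a gene without a listed peak is only without a peak among those analysed. Neither list gives read counts, so the sequencing depth is unknown.

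Peaks of the 2 lists were paired in order along each chromosome where widths differed by at most 150 bp and scores by at most 0.25 on the natural log scale. Gene identifiers of the annotated table were matched to the RefSeq gene table by gene number (2524 of 2537 genes, 99.5%). A promoter peak was a peak with an absolute distance of at most 1000 bp to the TSS in the authors' annotation. That distance is 0 for a peak overlapping the TSS, whereas the plan named the peak centre or summit. The 22 gene lists were fixed before the data were examined; they cover chaperone families, other stress responses, NK cell genes, housekeeping genes and markers of other cell types, and 583 of their 584 entries were matched. Some genes stand on more than 1 list. The share of list genes with a promoter peak was compared with that of all other protein-coding genes (20037 in all) by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 22 lists and a threshold of 0.05. Scores were compared by a two-sided permutation test of medians with 100000 resamples, adjusted over the 16 lists with at least 2 promoter peaks. Shares carry 95% Wilson intervals. Intervals and tests describe the peaks and genes of 1 library: they contain no error between cultures, and no replicate check of any value was possible.

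After the data were seen, further analyses were added. The 5 chaperone lists were pooled, their promoter peaks were compared in score with the other promoter peaks, the same was done for each list, and promoter shares were taken among the 100 strongest peaks and by deciles of score. List genes were counted when they were the nearest gene of any peak, with 10000 random lists matched on gene territory (the span between the midpoints of the neighbouring coding genes, in 20 classes; one-sided) as a second reference. The hg38 list was also compared with RefSeq gene boundaries, counting every coding gene with either end within 1000 bp of a peak centre, because the RefSeq table used gives no strand; 10 random placements of the peaks between the first and last coding gene of each chromosome gave the background. In simulations with the number of genes and the promoter share of the annotated table, lists of 25 genes with a 6-fold higher share were called at an unadjusted p under 0.05 in 97.5% of 200 draws, lists with a 3-fold higher share in 50%, and unchanged lists in 1.50%.

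The genes named were set by rule: the 20 coding genes with the strongest promoter peak, the 5 strongest peaks farther away, and up to 4 strongest members of each list with a promoter peak. Genes sharing a promoter on hg38 and the NK genes named for distal peaks were chosen after their values were seen. Alternatives were the 1705 peaks with a score of at least the median, promoter distances of 3000 bp and 5000 bp, autosomes and X alone, and the hg38 list with RefSeq boundaries. Planned searches for heat shock elements and other motifs, and a background of CpG-rich promoters, needed a genome sequence, which was not used here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.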

Results

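HSF1 occupancy was profiled in NK-92 MI cells after 1 h at 42 °C, to locate the genes that this factor contacts in an NK cell line under heat stress. The annotated table held 3396 peaks and the hg38 list 3438 peaks. Peaks of the annotated table were 303 to 2611 bp wide (median 427 bp) and together covered 1687 kb. Their scores ran from 3.05 to 41.3 with a median of 6.19 and quartiles of 5.30 and 7.97, and 132 peaks (3.89%) had a score over 20. Of these peaks, 3357 (98.9%) had a partner of similar width and score in the hg38 list. All values come from 1 library without a replicate; its title numbers it 2, and no library numbered 1 of the heat-shocked cells was analysed here.

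Many of the strongest HSF1 promoter peaks lay at chaperone genes. Of the 20 strongest peaks, 17 lay within 1000 bp of a TSS. Of the 20 coding genes with the strongest promoter peak, 9 belonged to the chaperone lists: HSPH1 (score 32.9; chromosome 13, 31735689 to 31736831 on hg19), an HSP110 exchange factor of HSP70; STIP1 (32.4; chromosome 11, 63952645 to 63954152), the adaptor between HSP70 and HSP90; DNAJB6 (32.1) and DNAJB1 (29.5), HSP40 cochaperones; HSP90AA1 (32.0; chromosome 14, 102552724 to 102554087) and HSP90AB1 (29.1), the cytosolic HSP90 genes; CCT4 (31.0), a chaperonin subunit; PTGES3 (29.4), the HSP90 cochaperone p23; and HSPA8 (29.3), the constitutive HSP70. ZFAND2A, an arsenite- and heat-inducible proteasome regulator, had a score of 38.8, and the polyubiquitin gene UBB had 31.6. All 20 of these promoter peaks overlapped the TSS, with widths between 796 and 2063 bp.

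Several of the strongest promoter peaks sat between neighbouring genes, of which the annotated table names 1; the neighbours given here were chosen after the values were seen. The strongest of all (score 41.3; chromosome 22, 41252275 to 41253275 on hg19, 40856271 to 40857271 on hg38) was assigned to XPNPEP3, and on hg38 it also lay within 1000 bp of a boundary of ST13, which encodes the HSP70-interacting protein Hip. The peak assigned to the read-through gene HSPE1-MOB4 (38.6; chromosome 2, 197499602 to 197500624 on hg38) lay within 1000 bp of HSPD1 and HSPE1, the mitochondrial chaperonin and its partner. That assigned to MRPL18 (38.1; chromosome 6, 159788956 to 159790677 on hg38) lay within the same distance of the chaperonin gene TCP1. USPL1 (41.0) shared its peak with a boundary of HMGB1, ABHD3 (35.2) with MIB1 and FBXO15 (30.5) with TIMM21. CCT4 (31.0), counted above among the chaperone genes, shared its peak with COMMD1. The remaining genes among the 20 were UBE2D3 (34.9), a ubiquitin-conjugating enzyme, RBM23 (30.9) and ACOT7 (29.6).

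In 3 of the 5 chaperone lists, the share of genes with an HSF1 promoter peak passed the test as higher than among other coding genes. Over all 5 lists together, 32 of 125 genes had a promoter peak (25.6%, 95% Wilson interval 18.8 to 33.9%). The share of all other coding genes was 5.98% (two-sided Fisher's exact p = 2.26e-12, odds ratio 5.41). The HSP90 family and its cochaperones had the highest share, 12 of 23 genes (52.2%), led by STIP1, HSP90AA1, PTGES3 and HSP90AB1, with an adjusted Fisher's exact p of 3.99e-08. Of the HSP70 family and its exchange factors, 8 of 25 genes had a promoter peak (32.0%, adjusted Fisher's exact p = 0.000583), led by HSPH1, HSPA8, HSPA4 (25.6) and the strictly inducible HSPA6 (17.3). The other 17 genes had no promoter peak among those analysed; since some peak numbers were not analysed here, and near-identical HSP70 genes can share reads, the count of 8 can be too low, and no absence of HSF1 can be read from it. Of the HSP40 family, 8 of 46 genes had one (17.4%, adjusted Fisher's exact p = 0.0169), led by DNAJB6, DNAJB1 and DNAJA1 (24.4). The chaperonin and prefoldin list did not pass (4 of 21 genes, 19.0%, adjusted Fisher's exact p = 0.0717); with the hg38 list and every coding gene counted that had either end within 1000 bp of a peak centre, 10 of its 21 genes (47.6%) had a peak and the list passed (adjusted Fisher's exact p = 2.20e-06). None of the 10 small heat shock proteins and crystallins had a promoter peak, which with so few genes allows a share of up to 27.8% (Wilson).

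Chaperone promoter peaks were also stronger than other promoter peaks. The 34 chaperone peaks had a median score of 18.4 (quartiles 8.68 and 28.3), against 5.95 (quartiles 5.15 and 7.26) for the other 1347 promoter peaks. The difference of medians was 12.4 (two-sided permutation p = 1e-05, the smallest that the resamples can give). A score over 20 was reached by 16 of the 34 chaperone peaks (47.1%) and by 49 of the other 1347 (3.64%).

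**Figure D1:**
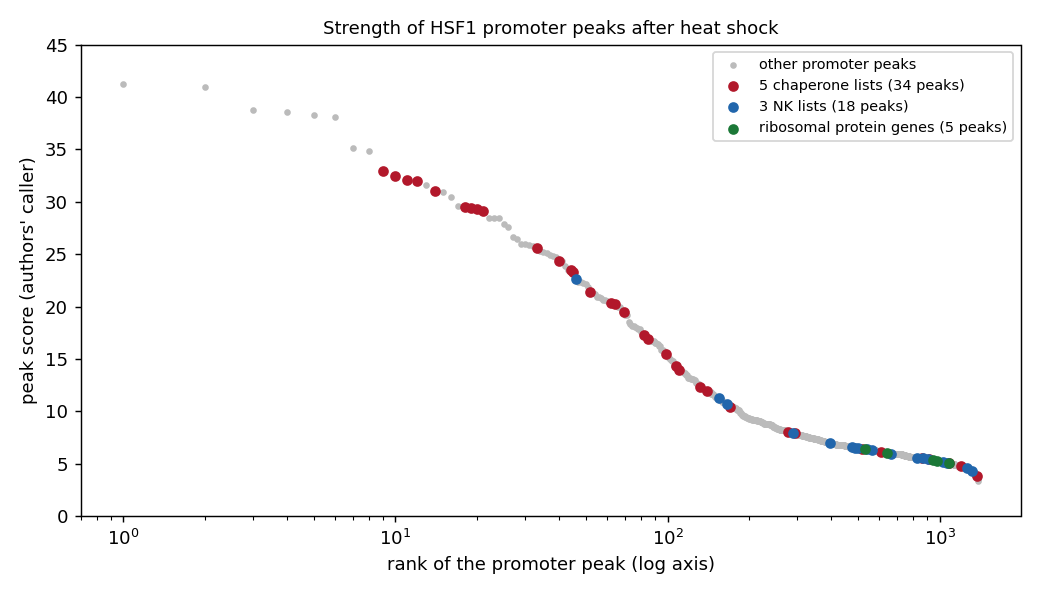
Score of each of the 1381 promoter peaks (vertical axis, score of the authors' caller) against its rank (horizontal log axis), coloured by gene list. Chaperone peaks (34) lie mostly among the highest ranks, while the 18 peaks of the NK lists and the 5 of ribosomal protein genes have mostly scores under 10 (1 NK peak, at JAK3, has a score of 22.6).

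Promoters of other stress genes had peaks too. Of the heat shock factors and regulators, 6 of 19 genes had a promoter peak (31.6%, adjusted Fisher's exact p = 0.00228), led by ZFAND2A, CCDC117 (25.8), the HSP70 nuclear import carrier HIKESHI (19.2) and DEDD2 (18.3). Of the immediate early genes, 9 of 26 had one (34.6%, adjusted Fisher's exact p = 0.000151), led by the phosphatase gene DUSP1 (24.9), the AP-1 gene JUN (15.9), IER5 (12.3), which is on both lists, and KLF2 (10.2). Of the oxidative stress genes, 7 of 23 had one (30.4%, adjusted Fisher's exact p = 0.00175), with the strongest at SOD1 and PRDX1 (both 10.8). Their median scores, 6.89 for the immediate early genes and 6.46 for the oxidative stress genes, did not pass the test against other promoter peaks (adjusted permutation p = 0.249 and 0.679). The shares are set against all other coding genes, whether or not these are active in the cells. Open promoters recovered without HSF1 can therefore not be told apart from HSF1 contact by share alone. This limit holds for the share of every list. The heat shock factors and regulators had a median of 18.3, above that of other promoter peaks (adjusted permutation p = 0.00165). The DUSP1 peak lay 916 bp from the TSS in the annotated table. On hg38 no peak centre lay within 1000 bp of a boundary of DUSP1.

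Lists of general protein turnover and growth showed a mixed picture. Glycolysis genes passed (5 of 22, 22.7%, adjusted Fisher's exact p = 0.0225) with 1 strong peak, at PGK1 (26.7), and a weaker one at LDHA (8.92); the list did not pass among the 1705 peaks with a score of at least the median (9.09%, adjusted Fisher's exact p = 0.243) or with RefSeq boundaries on hg38 (13.6%, adjusted Fisher's exact p = 0.298). Proteasome subunits (6 of 44, 13.6%, adjusted Fisher's exact p = 0.0907) and ubiquitin and autophagy genes (5 of 29, 17.2%, adjusted Fisher's exact p = 0.0644) did not pass, although UBB and UBQLN1 (28.4) had strong peaks. With RefSeq boundaries on hg38 both lists passed (adjusted Fisher's exact p = 0.0409 and 0.0218). Among the 1705 peaks with a score of at least the median, the proteasome share was 2.27%, against 2.75% of other coding genes (adjusted Fisher's exact p = 1), and at 5000 bp that list did not pass (adjusted Fisher's exact p = 0.215). Genes of the endoplasmic reticulum stress response (2 of 26, 7.69%) and cytosolic ribosomal protein genes (4 of 75, 5.33%) had shares near that of other coding genes.

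NK cell genes carried HSF1 peaks both at promoters and at a distance. Of the cytotoxic effectors and cytokines, 7 of 26 genes had a promoter peak (26.9%, adjusted Fisher's exact p = 0.00228), with the strongest at the chemokine gene CCL3 (10.7) and at NKG7 (7.96), a cytotoxic granule protein. CCL3 has near-identical copies that can share reads, so its value is uncertain. Of the NK transcription factors and cytokine signalling genes, 8 of 32 had one (25.0%, adjusted Fisher's exact p = 0.00228), led by the cytokine receptor kinase JAK3 (22.6) and by IL12RB2 (11.3), a chain of the interleukin-12 receptor. The NK receptors and adaptors had 2 of 32 (6.25%), KLRD1 and KIR2DL4, against 6.10% of other coding genes; KIR2DL4 belongs to a family of similar genes that can share reads. The share of this list was 18.8% at 5000 bp (adjusted Fisher's exact p = 0.0501) and 0% with RefSeq boundaries on hg38 (adjusted Fisher's exact p = 0.428). The median scores of the 3 NK lists, between 5.80 and 6.37, did not pass the test against other promoter peaks (adjusted permutation p between 0.679 and 0.895).

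Counted at any distance, 45 of the 90 NK genes (50%) were the nearest gene of a peak, against 11.1% of all coding genes. This held for the cytotoxic effectors (14 of 26, 53.8%), the receptors (13 of 32, 40.6%) and the transcription factors and cytokine signalling genes (18 of 32, 56.3%), with adjusted Fisher's exact p of 7.92e-07, 7.37e-05 and 6.73e-09. The highest share was that of the immediate early genes (17 of 26, 65.4%, adjusted Fisher's exact p = 1.41e-09), and the HSP90 list (52.2%), the heat shock factors and regulators (47.4%), the oxidative stress genes (43.5%) and the HSP70 list (32.0%) passed too. With peaks over 1000 bp from the TSS alone, 4 lists passed: the immediate early genes (61.5%) and the 3 NK lists (34.6% of effectors, 34.4% of receptors and 50% of transcription factors and signalling genes), with adjusted Fisher's exact p of at most 6.84e-05. The heat shock factors and regulators (21.1%, adjusted Fisher's exact p = 0.0772), the HSP90 (8.70%) and the HSP70 (4.00%) lists did not pass there. Of the 88 peaks nearest to these genes, 70 lay over 1000 bp from the TSS, at a median distance of 19547 bp. The genes named here were chosen after their values were seen. GZMB, the gene of the serine protease granzyme B, had 4 such distal peaks, the strongest (13.5) 58615 bp away. FASLG, the gene of a death receptor ligand, had 4, the strongest (10.3) at 15865 bp. RUNX3 had 9 peaks, 1 of them at its promoter, with the strongest (15.5) at 130059 bp. IL2RB had 4 peaks, 1 of them at its promoter, with the strongest (18.9) at 14381 bp.

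Genes listed as markers of other lineages served as a reference. Whether the NK-92 MI cells transcribe any of them was not examined. T cell markers had promoter peaks at 2 of 16 genes (12.5%, adjusted Fisher's exact p = 0.431), CD3E and BCL11B, and were the nearest gene of a peak in 4 of 16 (25.0%, adjusted Fisher's exact p = 0.185). With peaks over 1000 bp from the TSS alone their share was also 25.0%, against 6.01% of other coding genes. This was just short of the threshold (adjusted Fisher's exact p = 0.0585). No promoter peak was found among 12 B cell markers, 15 myeloid markers or the 20 genes each of the neuronal, liver and muscle lists. At any distance, 1 myeloid marker and none of the 60 neuronal, liver and muscle genes had a peak, which allows a share of up to 6.02% (Wilson).

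**Figure D2:**
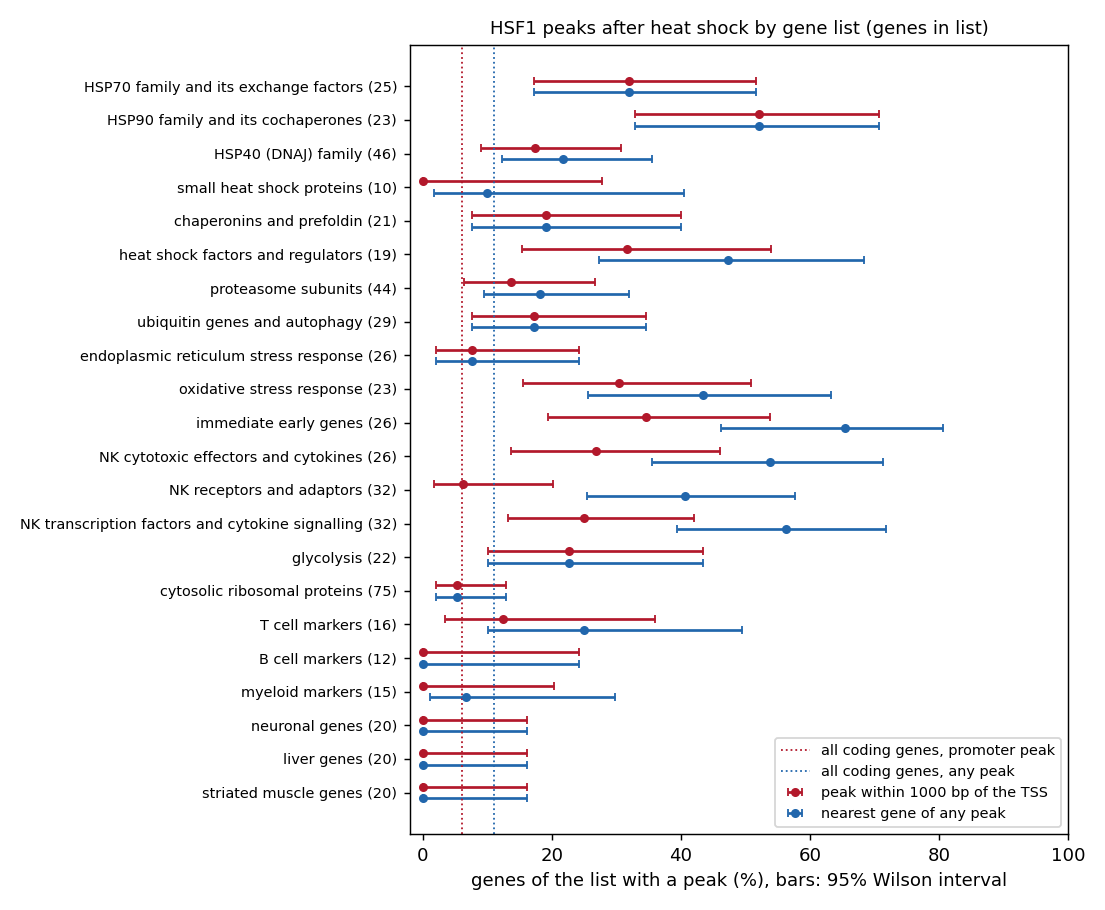
Percentage of the genes of each of the 22 lists with a peak within 1000 bp of the TSS (red) and of those that are the nearest gene of any peak (blue), with 95% Wilson intervals; dotted lines mark all coding genes (6.10% and 11.1%). The HSP90 list has the highest promoter share (52.2%) and the immediate early genes the highest any-distance share (65.4%), while the 3 NK lists have any-distance shares of 40.6 to 56.3%.

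Most HSF1 peaks lay away from promoters. Of the 3396 peaks, 1381 (40.7%, 95% Wilson interval 39.0 to 42.3%) lay within 1000 bp of a TSS, and 922 overlapped one. Intergenic peaks made up 26.0% and intronic peaks 24.7%, while 1460 peaks (43.0%) lay over 10000 bp from the nearest TSS. On hg38, 1118 of 3438 peaks (32.5%) had a boundary of a coding gene within 1000 bp. In 10 random placements this share had a mean of 2.76% and was at most 3.29%. The plan named placements that avoid assembly gaps. Those used did not avoid them, which can lower the random share. The strongest distal peaks were an intergenic peak 16672 bp from APOH (33.6), a peak in intron 4 of 14 of PRKCA (31.8; chromosome 17, 64563076 to 64563787 on hg19), intergenic peaks nearest to GALNT2 (30.1) and LINC00707 (29.3), and a peak in intron 1 of 5 of AGTRAP (29.5).

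Promoter peaks had a lower median score than distal peaks but were more frequent among the 100 strongest peaks. Their median score was 5.97 against 6.40 for distal peaks, a difference of -0.43 (two-sided permutation p = 1e-05, the smallest that the resamples can give). Promoter peaks made up 51 of the 100 strongest peaks and 40.4% of the others (unadjusted two-sided Fisher's exact p = 0.0384). The cut at 100 peaks was set after the data were seen. By deciles of score, the promoter share was 48.2 to 50.7% in the 3 weakest, 29.8% in decile 9 and 37.9% in the strongest. Within the 1705 peaks with a score of at least the median the difference of medians was -0.30 and did not pass (permutation p = 0.0608).

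**Figure D3:**
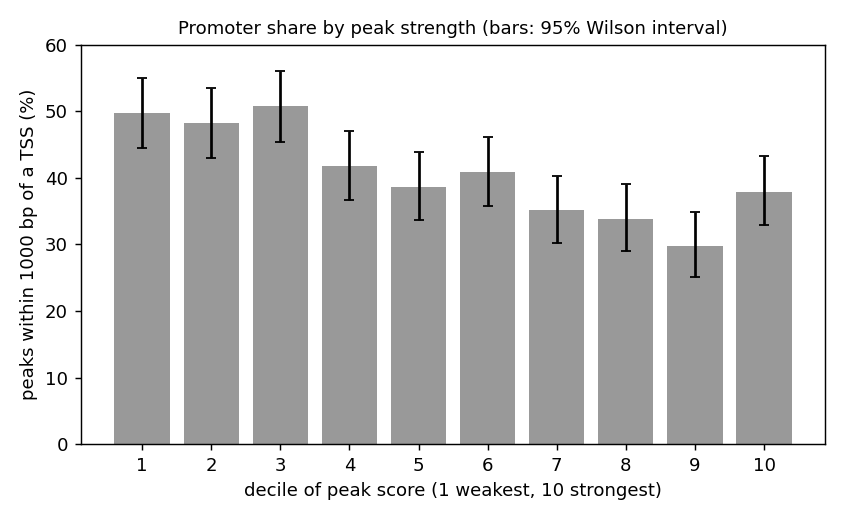
Percentage of peaks within 1000 bp of a TSS (vertical axis) by decile of peak score (horizontal axis, 339 or 340 peaks each), with 95% Wilson intervals. The share is 48.2 to 50.7% in the 3 weakest deciles, 29.8% in decile 9 and 37.9% in the strongest.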

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

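The tests in this part were chosen after the results were seen. The hg38 list, which the gene comparisons mainly did not use, held 81 peaks with no partner of similar width and score in the annotated table, and 39 peaks of the table had none on hg38; their median scores were 5.60 and 5.62. Not all were weak: the strongest unpaired hg38 peak had a score of 35.6, and 2 of the 81 had a score over 20.

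Within these, all 5 hg38 peaks in the first 2.7 Mb of chromosome X (scores 5.07 to 11.0), where X and Y share sequence, lacked a partner, and the table listed 0 peaks there. The other 72 hg38 peaks of X all had a partner (two-sided Fisher's exact p = 5.06e-08). Peaks left out of the table with their numbers are argued against: 0 peak numbers were skipped just before its first X peak. A candidate explanation is that the X and Y copies of this sequence were treated differently in the builds used for alignment. Reads matching both copies could then be lost for the table or listed under Y. Peaks were paired within a chromosome only, so peaks on Y were not compared with these 5. The table does hold peaks on Y: its promoter share was 40.6% on autosomes and X alone and 40.7% on all chromosomes. The test shows where the unpaired peaks lie and not why. How reads matching both copies were handled is not given in the sources used here, so the explanation stays an open hypothesis. No biological explanation was tested.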

How the results depend on the processing

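Of 91 results recomputed under alternatives, 75 were unchanged by the following rules. Tested results, list shares among them, kept their direction and their side of the threshold, whatever their size. The promoter share of peaks stayed within its interval, and counts of lists stayed within 1.5 times. Part of the 75 was fixed in advance: a list without a promoter peak could gain none among the stronger peaks, a subset of the same peaks. Of the others, 4 lists that passed neither before nor after turned direction against other coding genes: proteasome subunits (2.27% against 2.75%) and T cell markers (0% against 2.75%) in the 1705 peaks with a score of at least the median, and NK receptors (0% against 6.39%) and ribosomal proteins (9.33% against 6.37%) with RefSeq boundaries on hg38. At 5000 bp the NK receptor share was 18.8%, short of the threshold (adjusted Fisher's exact p = 0.0501). The alternatives on hg38 and those on peaks at any distance were added after the data were seen. The promoter share of 40.7% became 35.5% in the 1705 peaks with a score of at least the median, 45.6% at 3000 bp and 49.5% at 5000 bp. A related but different share, that of hg38 peaks with either end of a coding gene within 1000 bp of the centre, was 32.5%. This alternative changes the list, the build, the gene assignment and the distance measure together. In the annotated table any peak that overlaps the TSS has a distance of 0. In those 1705 peaks, the chaperonin list passed at 14.3%, the glycolysis list did not at 9.09%, and the difference between promoter and distal peaks (-0.30) did not pass; the cause was not tested. With RefSeq boundaries on hg38, the chaperonin (47.6%), proteasome (15.9%) and ubiquitin and autophagy lists (20.7%) passed and the glycolysis list (13.6%) did not; 8 of the 9 lists that passed in the table passed there too. Of the 8 lists that passed at any distance, all 8 passed against random lists of like territory; with peaks over 1000 bp from the TSS alone, 4 lists passed, the 3 NK lists and the immediate early genes. Searches for heat shock elements and control motifs, dinucleotide-shuffled windows and CpG-rich promoters were not run, since they need a genome sequence. No paired analysis was possible because 1 library was analysed. Without read counts, depth cannot be weighed, and a gene without a peak may lie under the caller's unstated threshold; 3 of the 5 chaperone lists passed in the table and 4 with the 47.6% share of chaperonins on hg38.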

Other observations

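The analyses in this part were chosen after the data were seen. Among genes that do not code for proteins, the strongest promoter peak lay at NEAT1, the long noncoding RNA that scaffolds paraspeckles (score 38.3; chromosome 11, 65188585 to 65190525 on hg19), with a further one at PTOV1-AS1 (25.2). Some genes collected many peaks: XYLT1 was the nearest gene of 11 peaks over 577 kb of chromosome 16, none of them at its promoter, RIN3 of 9 over 97.1 kb of chromosome 14, and RUNX3, a transcription factor of cytotoxic lymphocytes, of 9 over 184 kb of chromosome 1. Their median scores were 5.72, 7.97 and 6.99.

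Of the chaperonin and prefoldin genes, 6 (HSPD1, HSPE1, TCP1, CCT3, CCT5 and CCT6A) had no promoter peak in the annotated table but had a peak at a gene boundary on hg38, with scores of 12.1 to 38.5. For 6 of these 6 the paired peak of the table was assigned to another gene and overlapped that gene's TSS: HSPE1-MOB4 for HSPD1 and HSPE1, MRPL18 for TCP1, TSACC for CCT3, ATPSCKMT for CCT5 and PSPH for CCT6A. Because these genes were picked for lacking a peak of their own in the table, any paired peak had to carry another gene, so this count tests no explanation. Which of the genes at a shared promoter HSF1 acts on was not tested.

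The excess of peaks near NK genes is a pattern with several possible explanations, and with peaks over 1000 bp from the TSS alone the immediate early genes (61.5%) were the 1 other list that passed. T cell markers fell just short of the threshold there (25.0% of 16 genes, adjusted Fisher's exact p = 0.0585). Heat shock factors and regulators did not pass either (21.1%, adjusted Fisher's exact p = 0.0772). For peaks at any distance, promoter peaks included, large gene territories alone are argued against. The largest adjusted one-sided p of a permutation of list membership among genes of like territory was 0.000367. It was the smallest that the random lists gave. Observed were 18 transcription factor and signalling genes against a mean of 4.12, 14 effectors against 2.75 and 13 receptors against 3.29. No such permutation was run with peaks over 1000 bp from the TSS alone. Recovery of any highly transcribed gene stays open. Of ribosomal protein genes, 5.33% were the nearest gene of a peak (upper 95% bound 12.9%), below the lowest lower bound of the NK lists (25.5%). That speaks for this class of genes only. The intervals of the glycolysis (22.7%, 10.1 to 43.4%) and proteasome lists (18.2%, 9.51 to 32.0%) reach above that bound, and no transcript levels were used here. Open NK chromatin recovered without HSF1 cannot be told apart from HSF1 contact there, because the input and the other immunoprecipitation were not analysed here. Of the 88 peaks near NK genes at any distance, 1 (1.14%) had a score over 20, against 132 of all 3396 peaks (3.89%). Of the 34 chaperone peaks, all at promoters, 16 had one. The absence of peaks near the 60 neuronal, liver and muscle genes is consistent with either.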
